A study of Rattus norvegicus with 21 samples.

How the data were processed

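Gene expression was measured by RNA-seq in 21 rat liver samples, 12 from Wistar rats and 9 from Sprague Dawley rats, with 3 samples in each of 7 groups. Per the labels' protocols, RNA was extracted with a column kit and libraries were made with a template-switching mRNA kit. The aligner and the counter are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10, whereas the deposited tables hold Ensembl rat gene identifiers with rat chromosomes and coordinates. Coordinates are therefore given as the tables hold them, for a rat build that the tables do not name.

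The authors deposited 1 table for the Wistar samples and 1 for the Sprague Dawley samples, each with 32623 genes. Per the file headers, each table gives a count and an FPKM value per gene and sample. The FPKM values were normalized by the authors for transcript length and for the fragments of each sample. The deposited counts are whole numbers, were not normalized, and their low values pile up at multiples of 4. A sequenced fragment was therefore taken to be worth about 4 count units, and the counts were treated as estimated counts that were already whole. A value of 0 in all libraries of a group was read against a floor of 3 fragments, 12 count units, per library. That floor covers counting error only. Reads shared between near-identical genes could not be separated in these tables, so values for gene families such as the glutathione S-transferases, cytochromes P450 and ribosomal protein copies are uncertain, as is the value of the Spsb2 entry. The library kit does not mark strand in the labels, so overlapping and antisense genes are uncertain too.

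Total counts ran from 52054644 to 75118153 per sample. The number of genes at an FPKM of at least 1 ran from 10250 to 11082 per sample. Depth differed little between groups, and the spread between samples, with a biological coefficient of variation of 0.404 in the Wistar and 0.379 in the Sprague Dawley table, set the precision.

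Samples were grouped by their labels. The labels do not say that samples came from separate animals, so p-values measure the spread between these samples. No sample was left out, and no pair of samples was close enough to be a library deposited more than once. The highest correlation of log values was 0.961 within a group and 0.958 between groups, and at most 1.9% of counts were identical.

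The gene lists, the tests, the named-gene rule and most of the alternatives were chosen before the data were examined. The plan was to use limma on FPKM values, with edgeR in its place if the tables held counts. The tables held counts, so the main test was edgeR 4.0.16 in R 4.3.3. Each table was fitted alone, with a mean per group, TMM normalization and the filterByExpr filter at a minimum count of 10. This left 15416 genes in the Wistar and 15019 in the Sprague Dawley table. Contrasts were tested with the two-sided quasi-likelihood test, and Benjamini-Hochberg adjusted p below 0.05 counted as a call. Strain, the oldest age and the table are the same split, so the tables were never fitted together. Log2 fold changes are from edgeR, and levels are the deposited FPKM values as mean ± SD.

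There were 44 gene lists on lipid, amino acid and hormone pathways, sex, time of day, stress, immunity and markers of other cell types, with 703 of 742 symbols matched. Lists with at least 5 tested genes, 40 in each contrast, were tested with camera from limma 3.58.1 at its preset correlation of 0.01 and adjusted over the lists. The same test with a correlation estimated from the data called 0 lists in every contrast, whereas at the preset correlation 9 to 19 lists were called. The rotation test fry called 0 to 4 lists in the contrasts of early weaning and leucine and 17 between ages.

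Named genes followed a fixed rule. For the early weaning contrasts and for leucine against no leucine, it takes the 6 called genes of largest rise and of largest fall among genes at an FPKM of at least 1 in either group whose samples did not overlap. It adds the 4 members of smallest p of each called list and a panel of lipid and hormone genes, of which some are not reported here. Where fewer genes were called, those of smallest p stand in their place as values that did not pass. For the other contrasts, it takes the 5 called genes of smallest p in each direction. A gene outside this rule is named as one chosen after its values were seen.

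The tests were tested on simulated data drawn from the real means, library sizes and spread. Changed genes came from those above the median level, and each gene was drawn independently. The shares recovered therefore do not cover less expressed genes or outlying libraries. Of 100 genes changed 2-fold, edgeR recovered 52 in the d211 contrast over 14603 genes, 45 in the leucine contrast over 14604 genes, 31 at d23 over 15056 genes and 24 at d63 over 15045 genes. Of 100 genes changed 4-fold it recovered 95, 93, 92 and 89. EdgeR called 14, 10, 6 and 4 unchanged genes, whereas DESeq2 called 68, 48, 55 and 37. DESeq2 also recovered more of the genes changed 2-fold, at 80, 67, 58 and 49. The contrasts that share the early weaned libraries at d211 were also compared with sets simulated on log CPM with no effect of leucine.

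Alternatives were DESeq2 1.42.0, DESeq2 size factors within edgeR, no filter, limma on log2(FPKM + 1) with another pseudocount, filter, TPM and median-of-ratios scaling, a fit of the compared groups alone, a fold minimum of 2, the replicate number as a block and leaving out each sample in turn. Chosen after seeing the data were a term for Y-linked expression, leaving out the 3 Wistar libraries that lack it, a term for clock gene level and counts divided by 4.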

Results

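Early weaning takes pups off milk before the usual age. Livers of early weaned and control Wistar rats were compared at d23, shortly after weaning, and at d63. Livers of Sprague Dawley rats were compared at d211, where a further early weaned group had drinking water with 1.5% leucine, a branched-chain amino acid. The series' title asks about beta-oxidation, cholesterol metabolism and obesity. Depth was even, at 52054644 to 75118153 total count units per library. Differences between groups were clearest at d211, where 108 genes passed the test between early weaned and control livers, against 2 at d23 and 0 at d63. These counts stand for different strains and spreads, and the difference between d211 and the earlier ages was not tested.

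At d211, early weaned livers had less of the amino acid catabolic enzyme Sds and more of Pmvk, a gene of cholesterol synthesis, than controls. Sds, serine dehydratase, fell by 5.01 on the log2 scale (SE 0.357, adjusted p = 0.00141), from 37.3 ± 13.6 to 1.33 ± 0.349 FPKM, and was lower in each of 3 early weaned libraries than in each control. Pmvk, which encodes phosphomevalonate kinase, rose by 1.62 on the log2 scale (SE 0.263, adjusted p = 0.04), from 21.9 ± 5.23 to 77.8 ± 16.7 FPKM, again without overlap. Hlf, a clock-controlled transcription factor, fell by 2.19 (SE 0.225, adjusted p = 0.0144), from 8.47 ± 2.33 to 2.12 ± 0.178 FPKM. Spsb2, a SOCS-box protein gene, had a count of 0 in all controls and 4.26 ± 0.475 FPKM in early weaned livers, at least 28.6-fold higher (adjusted p = 0.00141). Whether reads from similar sequences were placed at this entry could not be checked. Among Wistar livers it varied within groups too, from 0 to 3.81 FPKM in d63 controls and from 0 to 3.14 in d63 early weaned livers. In all, 63 genes rose and 45 fell out of 15019, and 85 of the 108 changed at least 2-fold.

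Other large rises on the log2 scale were Gstm3l (5.01, adjusted p = 0.0481), which resembles a mu-class glutathione S-transferase, the matrix protease Adamts5 (4.45, 0.032), the ubiquitin ligases Neurl3 (4.09, 0.0444) and Cblc (3.32, 0.0491), and the insulin receptor substrate Irs3 (2.63, 0.04). Gstm3l was uneven within the early weaned group, at 93.2, 6.82 and 128 FPKM. Large falls were the cytochrome P450 gene Cyp2b2 (−3.22, 0.0438), the steroid dehydrogenase Hsd17b2 (−3.07, 0.04), the sulfotransferase Sult2a1 (−2.76, 0.0357) and Clock (−2.52, 0.0354). None of these genes overlapped between the groups, which the rule for naming them required. The tables place Sds on chromosome 12 at 41620393 to 41627741 (ENSRNOG00000001388), Pmvk on chromosome 2 at 188784222 to 188793895 (ENSRNOG00000020696), Hlf on chromosome 10 at 77840568 to 77918191 (ENSRNOG00000002456) and Spsb2 on chromosome 9 at 20217278 to 20219209 (ENSRNOG00000047113). Exons are not marked in the tables, so the values are per whole gene.

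Cholesterol synthesis genes rose as a list (camera adjusted p = 1.67e-19; adjusted p = 0.231 with an estimated correlation). Of 25 tested members 24 were higher, with a median log2 change of 1.27. Only Pmvk passed over all genes, and 20 members rose when adjusted over the list alone. Values that did not pass over all genes were 1.29 for Mvk (adjusted p = 0.0572), 1.26 for Fdps (0.0705) and 1.27 for Cyp51 (0.0727). For the fatty acid and triglyceride synthesis list, 15 of 23 members were higher (median 0.42, camera adjusted p = 0.0032; adjusted p = 0.433 with an estimated correlation), and 6 rose and 1 fell when adjusted over the list alone. Acacb, an acetyl-CoA carboxylase, rose by 1.76 (adjusted p = 0.0446), and Dgat2, which makes triglyceride, fell by 1.28 (0.0444). This call ended without control replicate 3 (median 0.215) or early weaned replicate 3 (0.377) and with limma on FPKM (0.61), and the median was 0.748 without control replicate 2. Fasn had 2.15 (0.233) and Srebf1 −0.20 (0.884).

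**Figure D1:**
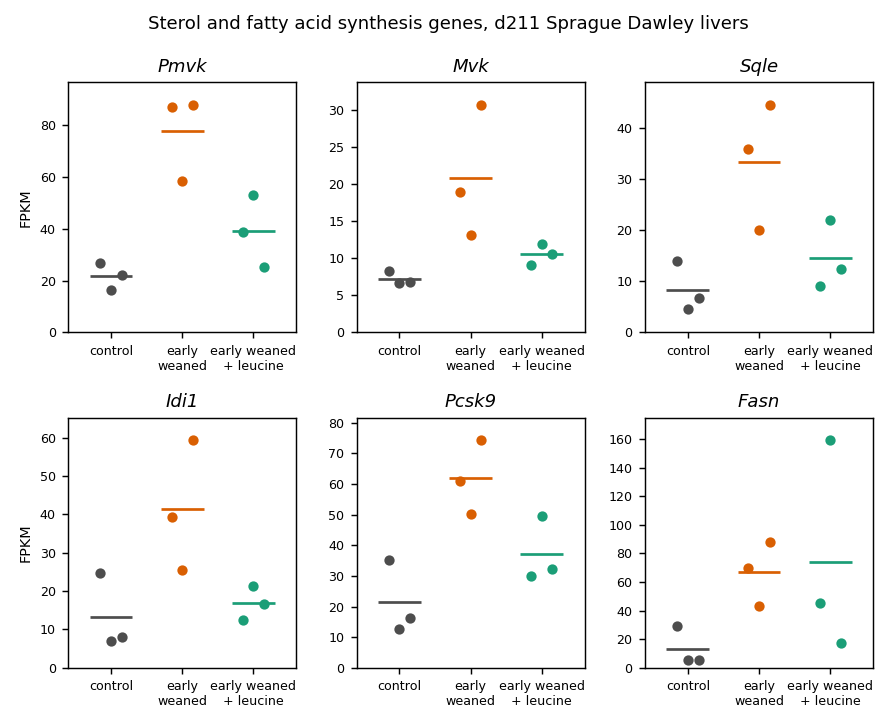
FPKM of 6 lipid genes in each d211 library (points) with group means (lines). Pmvk averaged 21.9 in controls, 77.8 in early weaned and 39.0 in leucine livers.

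Mitochondrial beta-oxidation genes fell as a list (camera adjusted p = 7.5e-09; adjusted p = 0.232 with an estimated correlation). All 20 tested members were lower, with a median log2 change of −0.396, which was −0.612 without early weaned replicate 2. None passed over all genes by edgeR, and 9 fell when adjusted over the list alone. Examples are −0.77 for the carnitine carrier Slc25a20 (adjusted p = 0.0651), −1.17 for Decr1 (0.0772), −0.77 for Hadha (0.087) and −1.03 for Cpt1a, the gatekeeper of fatty acid entry into mitochondria (0.247). The PPARα target list fell too, with 20 of 25 members lower (median −0.479, camera adjusted p = 6.28e-06; adjusted p = 0.232 with an estimated correlation). In it, 0 genes passed over all genes and 7 fell when adjusted over the list alone, with −1.62 for the hormone Fgf21 (0.0757) and −1.42 for the fatty acid hydroxylase Cyp4a1 (0.109). Ppara itself had −0.83 (0.251).

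Lists for sterol efflux and lipoproteins and for bile acids moved down. Of 27 sterol efflux and lipoprotein genes 26 were lower (median −0.345, camera adjusted p = 6.75e-09; adjusted p = 0.231 with an estimated correlation), with 0 passing over all genes and 11 falling when adjusted over the list alone. Examples are −3.90 for the sterol exporter subunit Abcg5 (adjusted p = 0.0584) and −0.80 for Lcat (0.055). Of 21 bile acid genes 17 were lower (median −0.485, camera adjusted p = 1.72e-06; adjusted p = 0.0887 with an estimated correlation), and 5 fell when adjusted over the list alone. Akr1c14 fell by 1.07 (0.0438), and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had −0.94 (0.552).

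Clock genes and drug-metabolizing genes also shifted. Of 19 circadian genes 13 were lower (median −1.05, camera adjusted p = 1.56e-07; adjusted p = 0.0887 with an estimated correlation), with 4 rising and 11 falling when adjusted over the list alone. Hlf, Tef (−1.72, adjusted p = 0.0357) and Clock fell, while Npas2, which pairs with the same partner as Clock, rose by 2.40 (0.0443). Of 22 xenobiotic genes 16 were lower (median −0.501, camera adjusted p = 1.72e-06; adjusted p = 0.231 with an estimated correlation), and Cyp2b2, Gsta2 (−1.36, 0.0397) and Gsta5 (−1.18, 0.0405) fell. Of 23 urea cycle and amino acid catabolism genes 18 were lower (median −0.386, camera adjusted p = 1.72e-06; adjusted p = 0.232 with an estimated correlation), with Sds the only gene that passed. Of 23 interferon-response genes 21 were higher (median 0.349, camera adjusted p = 0.000104; adjusted p = 0.292 with an estimated correlation), and the peptide transporter Tap1 rose by 1.46 (0.0493). The interferon median was 0.538 without early weaned replicate 2 and 0.202 without replicate 3.

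**Figure D2:**
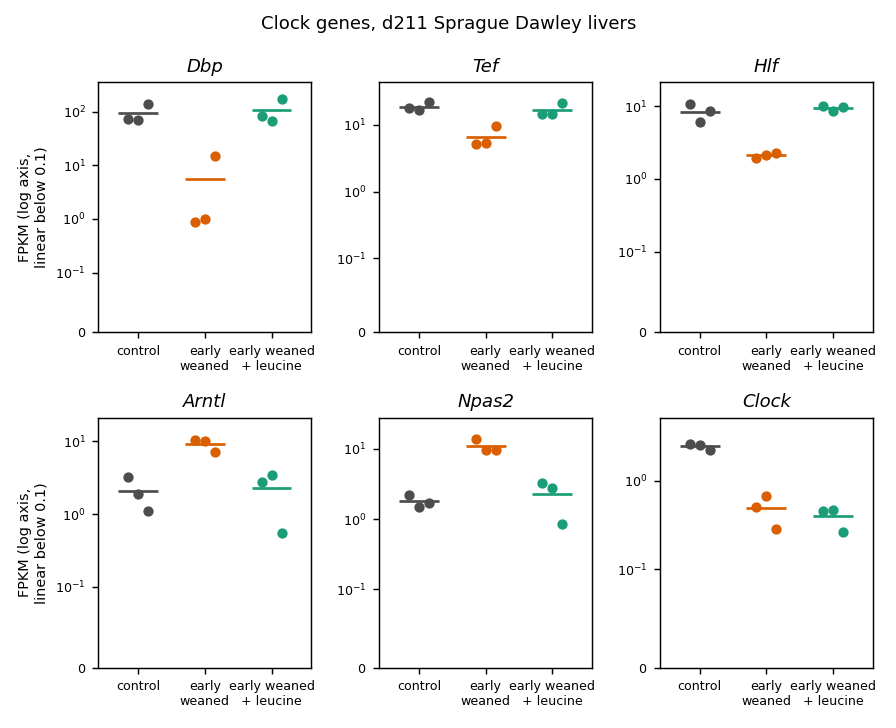
FPKM of 6 circadian genes in each d211 library (points) with group means (lines), on a log axis that is linear below 0.1. Hlf averaged 8.47 in controls, 2.12 in early weaned and 9.53 in leucine livers.

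Hepatocyte markers and mitochondrial transcripts moved with these groups. Of 9 hepatocyte marker genes 8 were lower (median −0.441, camera adjusted p = 2.63e-05; adjusted p = 0.231 with an estimated correlation), with −0.65 for Ttr (adjusted p = 0.0853) and −0.60 for Hnf4a (0.0903). All 13 members of the list of mitochondrially encoded genes were lower (median −0.505, camera adjusted p = 9.4e-07, or 0.278 with an estimated correlation), with −0.61 for Mt-nd1 (0.0899). The count of 108 rested on single libraries. It was 2 without early weaned replicate 1, 534 without early weaned replicate 2, 24 without early weaned replicate 3, 7 without control replicate 2 and 3 without control replicate 3, and among the named genes Spsb2 and Sds stayed past the threshold without each library in turn. Beside the 63 rises and 45 falls, limma gave 269 and 59 on FPKM and 552 and 63 on TPM, where the median of all genes moved by 0.179 and 0.251 on the log2 scale.

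Early weaned livers with leucine had more Sds and Hlf transcripts at d211 than those without, and less Jun and Tnfrsf12a. The glutathione S-transferase entries Gsta2 and Gsta5 were higher too. Sds rose by 5.98 on the log2 scale (SE 0.372, adjusted p = 0.000478), from 1.33 ± 0.349 to 76.2 ± 16.2 FPKM, and was higher in each of 3 leucine libraries than in each library without leucine. Hsd17b2 rose by 3.27 (0.0416) and Hlf by 2.32 (0.00908). Jun, an immediate-early transcription factor, fell by 2.39 (0.0294), from 57.7 ± 5.73 to 9.88 ± 1.88 FPKM. In all, 27 genes rose and 27 fell out of 15019, and 50 of the 54 changed at least 2-fold.

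Cda, cytidine deaminase, had a count of 0 in early weaned livers without leucine and 1.14 ± 0.131 FPKM with it, at least 2.73-fold higher (adjusted p = 0.0484). Other rises on the log2 scale were the receptor Edar (1.59, adjusted p = 0.0352) and the circadian repressor Cry2 (1.58, 0.0189). The falls included the TWEAK receptor Tnfrsf12a (−3.63, 0.0448), the phosphate carrier Slc34a2 (−3.19, 0.0492), Enc1 (−2.80, 0.0374), the nuclear receptor Ppard (−2.48, 0.0294) and the growth factor Pdgfa (−2.33, 0.0432). None of these genes overlapped between the groups, which the rule for naming them required.

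Urea cycle and amino acid catabolism genes rose as a list (camera adjusted p = 3.5e-19; adjusted p = 0.128 with an estimated correlation). Of 23 members 22 were higher, with a median log2 change of 0.616. Sds passed over all genes and 17 rose when adjusted over the list alone. Values that did not pass were 0.98 for the aminotransferase Got1 (adjusted p = 0.0547), 0.80 for arginase, Arg1 (0.0681), and 1.14 for Tdo2, which degrades tryptophan (0.073). Of 19 circadian genes 14 were higher (median 0.962, camera adjusted p = 2.15e-09; adjusted p = 0.0612 with an estimated correlation), with Hlf, Cry2 and Tef (1.51, 0.0492) rising. Of 22 xenobiotic genes 18 were higher (median 0.458, camera adjusted p = 1.36e-06; adjusted p = 0.326 with an estimated correlation), with rises of 1.46 for Gsta5 (0.0294) and 1.51 for Gsta2 (0.0344), and the median was 0.278 without leucine replicate 3.

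Lipid lists also differed with leucine. Of 25 cholesterol synthesis genes 20 were lower (median −0.57, camera adjusted p = 5.65e-05; adjusted p = 0.493 with an estimated correlation), with −0.83 for Pmvk (adjusted p = 0.183), and 0 passed over all genes by edgeR. Of 20 beta-oxidation genes 16 were higher (median 0.203, camera adjusted p = 0.0218; adjusted p = 0.493 with an estimated correlation), with 0.50 for Cpt1a (0.704). The beta-oxidation call ended without early weaned replicate 1 (median 0.2), early weaned replicate 3 (0.165) or leucine replicate 3 (0.0768), and the median was 0.307 without early weaned replicate 2. It also ended with the clock index as a term, chosen after seeing the data (0.0353), and with limma on TPM (0.0208) or without a filter (0.0513). Of 25 PPARα targets 16 were lower (median −0.309, camera adjusted p = 0.252), with a median of −0.125 without leucine replicate 1, and the list passed without leucine replicate 3 (−0.312). Of 27 sterol efflux genes 22 were higher (median 0.342, camera adjusted p = 5.15e-07; adjusted p = 0.326 with an estimated correlation), with 1.00 for Npc1 (0.0545) and 3.44 for Abcg5 (0.0806). Of 21 bile acid genes 17 were higher (median 0.38, camera adjusted p = 8.31e-05; adjusted p = 0.128 with an estimated correlation), with 1.77 for Cyp7a1 (0.318) and a median of 0.582 without early weaned replicate 2. Fasn had 0.31 (0.939).

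Interferon-response genes were lower with leucine in 17 of 23 cases (median −0.434, camera adjusted p = 0.000201; adjusted p = 0.362 with an estimated correlation), and Tap1 fell by 1.66 (adjusted p = 0.0492). Hepatocyte markers were higher (median 0.322, camera adjusted p = 0.00271; adjusted p = 0.362 with an estimated correlation), as were the stellate cell (0.449) and endothelial (0.39) markers, both at a camera adjusted p of 0.0218 (adjusted p = 0.362 and 0.493 with an estimated correlation). The endothelial call ended without early weaned replicate 2 (median 0.386), early weaned replicate 3 (0.241) or leucine replicate 1 (0.296), and the stellate call without leucine replicate 2 (0.42), with 0.29 without early weaned replicate 3. The count of 54 was 1 without early weaned replicate 1, 539 without early weaned replicate 2, 21 without early weaned replicate 3, 8 without leucine replicate 1, 6 without leucine replicate 2 and 18 without leucine replicate 3. Sds stayed past the threshold without each library in turn. Beside the 27 rises and 27 falls, limma gave 41 and 95 on FPKM and 42 and 131 on TPM, where the median of all genes moved by −0.13 and −0.162.

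Against controls, early weaned livers with leucine differed in 2 of 15019 genes. Spsb2 had a count of 0 in controls and 3.19 ± 1.07 FPKM with leucine, at least 21.5-fold higher (adjusted p = 0.00173). This entry was near all-or-none within the d63 Wistar groups as well. AC128792, listed as a microRNA gene (ENSRNOG00000036301), fell by 3.09 on the log2 scale (adjusted p = 0.00173), from 752 ± 182 to 92.2 ± 15.9 FPKM, in all 3 leucine libraries. All 25 cholesterol synthesis genes were higher (median 0.641, camera adjusted p = 5.93e-10; adjusted p = 0.478 with an estimated correlation), and 22 of 25 PPARα targets were lower (median −0.631, camera adjusted p = 3.32e-11; adjusted p = 0.207 with an estimated correlation). Fatty acid and triglyceride synthesis genes were higher in 19 of 23 cases (median 1.04, camera adjusted p = 3.88e-09; adjusted p = 0.306 with an estimated correlation). Without leucine replicate 2 the cholesterol median was 0.367 and the fatty acid median 0.531, and without leucine replicate 1 the PPARα median was −0.41. Beta-oxidation genes were lower in 16 of 20 cases (median −0.275, camera adjusted p = 2.99e-05; adjusted p = 0.478 with an estimated correlation). Endothelial markers were higher (median 0.364, camera adjusted p = 0.0109; adjusted p = 0.525 with an estimated correlation), as were Kupffer cell markers (median 0.357, camera adjusted p = 0.0389; adjusted p = 0.691 with an estimated correlation). Both calls ended without control replicate 1 (medians 0.224 and 0.0131) or leucine replicate 1 (0.255 and 0.237), the Kupffer call also without leucine replicate 3 (0.282), and without control replicate 2 the medians were 0.627 and 0.691. Circadian genes had a median of 0.217 (camera adjusted p = 0.711). The count was 5 without control replicate 1, 4 without control replicate 2 or leucine replicate 1, and 6 without leucine replicate 2 or 3, and both genes stayed past the threshold in each case.

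Most genes that differed between early weaned and control livers at d211 had the opposite sign under leucine. Of the 108 genes, 104 did, with a median of 0.75 of the change taken back. Past the threshold in both contrasts and in opposite directions were 26 genes, 12 that rose and then fell and 14 that fell and then rose, Sds, Hlf, Tef, Gsta2 and Tap1 among them. The clock index, a level of clock genes per library, ran from −4.58 to 2.77 in early weaned libraries. It ran from 6.46 to 8.95 in controls and from 6.63 to 10.79 with leucine. A difference in time of day or feeding at sampling could give opposite signs, and it was not told apart from leucine. Both contrasts use the same 3 early weaned libraries and could not be given separate ones, so opposite signs also arise with no effect of leucine.

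To measure that share, in a test chosen after seeing the data, 100 sets were simulated with an early weaning change and no effect of leucine, with the early weaned and the leucine libraries at their common mean, and 100 more with both at the early weaned mean. Deviations were mixtures of the observed ones, which keeps the correlation between genes, and calls were by limma on log CPM. The real libraries then gave 96.7% of called genes with the opposite sign, a median share taken back of 0.751 and 54 genes called in both contrasts in opposite directions. At the common mean the sets averaged 67.7%, 0.107 and 13.9 genes, and 8, 0 and 3 of 100 sets were as high as the real libraries. At the early weaned mean they averaged 61.4%, 0.0718 and 1.37 genes, and 0, 0 and 1 were as high. The highest share taken back was 0.638 in the first and 0.429 in the second. The sets took the observed group means as true. On average they called 748 genes (1 to 5250) at the common mean and 1320 (44 to 6990) at the early weaned mean. The real libraries gave 150. Fewer calls mean stronger selection, which can raise both shares, so these counts of sets can overstate an effect of leucine. The sets do not cover a difference in time of day or feeding at sampling. Across all genes, which are not independent replicates, the log2 changes correlated at −0.602 in this fit, as low in 2 and 3 of 100 sets. Those sets ran from −0.819 to 0.415 at the common mean and from −0.758 to 0.337 at the early weaned mean. Sets on log CPM without any group effect gave −0.501 (−0.538 to −0.467), but they drew each gene independently, so their range is too narrow to judge by. By edgeR, on which these sets were not run, the correlation was −0.532 (−0.636 to −0.437 without each library in turn).

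At d23, early weaned and control livers differed in 2 of 15416 genes. AABR07070810, described in the tables as a pseudogene of ribosomal protein L12 (ENSRNOG00000061579, chromosome 8, 85489553 to 85490050), fell by 2.16 on the log2 scale (SE 0.183, adjusted p = 0.00227), from 123, 153 and 114 FPKM in the control libraries to 29.6 ± 2.45, and was lower in each of 3 early weaned libraries. It has close copies, and LOC102555453, named as like the same protein, had −1.07 (0.17). Cd274, the immune checkpoint ligand, passed (adjusted p = 0.0406) with counts under the floor, so no fold is given. Among genes that did not pass, the log2 change was 1.83 for the transporter Abcg2 (0.0549), 2.67 for Vwa1 (0.0597) and −2.11 for the lipase inhibitor Angptl4 (0.17).

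Cell cycle and matrix genes were lower at d23 as lists. Of 25 cell cycle genes 23 were lower (median −2.58, camera adjusted p = 2.6e-05; adjusted p = 0.581 with an estimated correlation), and 9 fell when adjusted over the list alone, with −4.70 for Mki67 (adjusted p = 0.666). Of 20 matrix genes 17 were lower (median −0.405, camera adjusted p = 2.56e-05; adjusted p = 0.316 with an estimated correlation), as were 7 of 10 stellate cell and fibroblast markers (median −0.168, camera adjusted p = 0.0339; adjusted p = 0.316 with an estimated correlation). The stellate call ended without control replicates 1 (median −0.131), 2 (−0.195) or 3 (−0.125) or early weaned replicate 3 (−0.166). Of 26 PPARα targets 22 were lower (median −0.399, camera adjusted p = 0.000245; adjusted p = 0.696 with an estimated correlation), and 5 fell when adjusted over the list alone. Beta-oxidation genes had a median of −0.356 (camera adjusted p = 0.0999), with 0.09 for Cpt1a. Of 25 cholesterol synthesis genes 21 were higher (median 0.573, camera adjusted p = 0.000449; adjusted p = 0.721 with an estimated correlation). Of 22 xenobiotic genes 18 were higher (median 0.363, camera adjusted p = 0.000691; adjusted p = 0.581 with an estimated correlation). Acute phase genes were higher (median 0.159, camera adjusted p = 0.00218; adjusted p = 0.165 with an estimated correlation), with 1.60 for Orm1 (0.296). The cholesterol call ended without control replicate 1 (median 0.389), control replicate 3 (0.389) or early weaned replicate 2 (0.16), and the cell cycle call with limma on FPKM (−0.139). The PPARα median was −0.649, −0.629 and −0.633 without control replicates 1 and 2 and early weaned replicate 2, and the acute phase median 0.285, 0.0105 and 0.0537 without control replicate 2 and early weaned replicates 1 and 2. The beta-oxidation list passed without control replicate 1 (−0.474) or 2 (−0.61).

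A single d23 library stood apart beside these lists. Control replicate 3 had 70.5 FPKM of the fetal gene Afp, where the other d23 libraries had 0.59 to 9.49. Without it, 2 lists passed in place of 9, and 8 of the 9 calls ended, among them those of PPARα targets (median 0.124), cell cycle (−0.253), cholesterol synthesis (0.389), xenobiotic (0.271) and acute phase genes (0.14), while the beta-oxidation median was 0.165. Early weaned replicates 2 and 3 lack the Y-linked transcripts Eif2s3y and Kdm5d that the other d23 libraries have, and the labels do not give sex. With a term for Y-linked expression, chosen after seeing the data, AABR07070810 had −2.02 (SE 0.229, adjusted p = 0.0806). The cholesterol (0.056), xenobiotic (0.254), urea cycle (0.0601), glucocorticoid (0.272) and stellate (−0.311) calls ended with it. The cholesterol median turned to −0.235 without the 3 Wistar libraries that lack Y-linked expression. Over all alternatives the adjusted p of AABR07070810 ran from 3.49e-24 with DESeq2 to 0.231 without the 3 Wistar libraries that lack Y-linked expression, and it was 0.062 when d23 was fitted alone. The gene count was 6 without early weaned replicate 1, 4 without early weaned replicate 3, and 1 without control replicate 1 or 2 or early weaned replicate 2, with AABR07070810 past the threshold in each case.

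At d63, 0 genes passed by edgeR between early weaned and control livers, with 933 of 15416 at an unadjusted p under 0.05, 89 called by DESeq2 and 0 by limma on FPKM. The smallest p-values were for the transcription factor Zbtb16, at −4.45 on the log2 scale (adjusted p = 0.279), from 11.3 ± 4.59 to 0.48 ± 0.344 FPKM, and the globin gene Hba-a3, with a count of 0 in all early weaned libraries and 668, 110 and 1651 count units in the controls (0.279). It was at least 61.5-fold lower, or 29.1-fold without control replicate 3, and the share of counts from globin genes in these controls ran from 0.0403% to 0.543%. Upward, the smallest p-values were for Cyp1a1 (3.08, 0.48), Serpina4 (0.77, 0.48) and the circadian repressor Cry1 (1.80, 0.48). Srebf1 had 1.15 (0.717) and Cpt1a −0.57 (0.821).

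PPARα targets were lower at d63 in 21 of 26 cases (median −0.684, camera adjusted p = 2.29e-05; adjusted p = 0.454 with an estimated correlation), with −1.48 for Angptl4 (adjusted p = 0.505). Beta-oxidation (median −0.0575, 0.815) and cholesterol synthesis (0.0792, 0.555) lists did not pass. Branched-chain amino acid catabolism genes were higher in 19 of 20 cases (median 0.327, camera adjusted p = 1.04e-06; adjusted p = 0.311 with an estimated correlation), with 0.75 for Pcca, a subunit of propionyl-CoA carboxylase (0.48). All 33 respiratory chain genes were higher (median 0.255, camera adjusted p = 7.95e-08; adjusted p = 0.454 with an estimated correlation), as were 19 of 23 urea cycle and amino acid catabolism genes (median 0.378, camera adjusted p = 0.000328; adjusted p = 0.454 with an estimated correlation) and 14 of 18 circadian genes (median 0.53, camera adjusted p = 6.94e-05; adjusted p = 0.311 with an estimated correlation). The urea cycle call ended without control replicate 3 (median 0.258), and without early weaned replicate 3 the urea cycle median was 0.244 and the circadian 0.336. The cholesterol list passed in opposite directions without early weaned replicate 3 (−0.498) and without early weaned replicate 1 (0.371).

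Markers of other liver cells were lower at d63 beside these lists, with 9 of 9 endothelial markers (median −0.623, camera adjusted p = 1.03e-06; adjusted p = 0.311 with an estimated correlation) and 12 of 12 Kupffer cell markers (median −0.475, camera adjusted p = 0.000328; adjusted p = 0.454 with an estimated correlation). All 9 female-biased genes were lower (median −3.32, camera adjusted p = 1.29e-07; adjusted p = 0.311 with an estimated correlation), and 6 fell when adjusted over the list alone, while 8 of 9 male-biased genes were higher (median 0.543, camera adjusted p = 0.00306; adjusted p = 0.454 with an estimated correlation). Control replicate 2 lacks Eif2s3y and had 2370 FPKM of the female-biased Cyp2c12 and 0.34 of the male-biased Cyp2c11, and without it the female-biased median was −0.524 and the male-biased median 0.175, with a camera test that points down and does not pass; without control replicates 1 and 3 the male-biased median was 1.05 and 0.929. The Kupffer call ended without control replicate 1 (median −0.124) or early weaned replicate 1 (−0.337). The gene count was 3 without control replicate 1, early weaned replicate 1 or early weaned replicate 3, and 1 without control replicate 2.

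**Figure D3:**
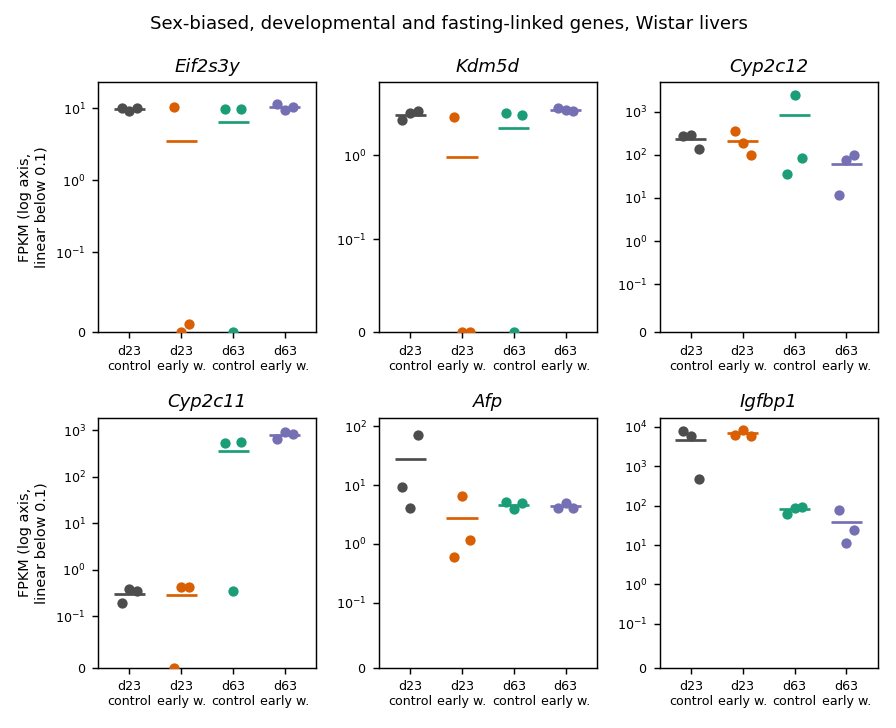
FPKM of 6 genes in each Wistar library (points) with group means (lines). Eif2s3y is near 0 in 3 libraries, and d63 control replicate 2 has 2370 FPKM of Cyp2c12.

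Control livers changed between d23 and d63 in 2710 of 15416 genes, 1229 up and 1481 down. Cd274 was at least 14.5-fold higher (adjusted p = 0.000145), the MHC class I gene RT1-CE5 rose by 3.03 on the log2 scale (0.000244) and Pigr, the polymeric immunoglobulin receptor, by 3.91 (0.000277), from 53.5 ± 9.48 to 801 ± 297 FPKM. The formin Diaph3 was at least 27.8-fold lower at d63 (0.000718), and Ica1 (−3.49, 0.000152) and the procollagen protease Adamts2 (−2.23, 0.000317) fell; none of these genes overlapped between the ages. Of 23 interferon-response genes 19 rose, 21 when adjusted over the list alone (median 2.37, camera adjusted p = 8.43e-18; adjusted p = 0.254 with an estimated correlation), and all 12 T and NK cell markers were higher, 5 past the threshold (median 2.21, camera adjusted p = 7.76e-05; adjusted p = 0.273 with an estimated correlation), as were all 8 B and plasma cell markers, 1 past it (median 2.9, camera adjusted p = 0.00609; adjusted p = 0.339 with an estimated correlation). In turn, 15 urea cycle genes fell (median −1.49, camera adjusted p = 4.81e-11; adjusted p = 0.273 with an estimated correlation). The count was 646 without d23 control replicate 1, 744 without replicate 2 and 6001 without replicate 3, and 859, 1221 and 953 without d63 control replicates 1, 2 and 3. The upward share of 45.4% was 59.6% with limma on TPM.

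The early weaning effect differed between d23 and d63 in 1 gene, AABR07070810 (adjusted p = 0.0319), with −2.16 at d23 and 0.12 at d63, and this call was lost in 8 of 12 refits without a library and with the replicate as a block. Across genes, which are not independent replicates, the early weaning changes correlated at 0.0904 (jackknife SE 0.0844) between d23 and d63, −0.0202 (0.0591) between d23 and d211 and −0.0704 (0.0985) between d63 and d211. The overlap between called genes was 0 in each pair, where 0.0043 were expected for d23 with d211, so the test has no reach there.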

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

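The tests of clock phase, feeding, the library without Y-linked expression, adult liver RNA and fasting were chosen only after the results were seen, whereas the splits of the samples were planned.

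A single gene and 13 lists stand out because the effect of early weaning differed between d23 and d63 in a test of the difference itself. AABR07070810, the ribosomal protein L12 pseudogene, had a difference of 2.27 on the log2 scale (−2.16 at d23, 0.116 at d63, adjusted p = 0.0319), and its call was lost in 8 of 12 refits without a library. The lists passed with camera at its preset correlation and not with an estimated correlation, where their adjusted p ran from 0.636 to 0.864.

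For metabolism, the median difference was −0.398 for cholesterol synthesis (0.573 at d23, 0.0792 at d63, adjusted p = 0.0405), 0.264 for branched-chain amino acid catabolism (0.0295 and 0.327, adjusted p = 0.00208), −0.517 for glucocorticoid targets (0.366 and −0.285, adjusted p = 0.000638) and 0.208 for the respiratory chain (0.0368 and 0.255, adjusted p = 0.00427). For growth and stress, it was 1.43 for cell cycle genes (−2.58 and −0.552, adjusted p = 0.00733) and −0.341 for the unfolded protein response (0.104 and −0.28, adjusted p = 0.00733). For cell types, it was 0.141 for hepatocyte markers (0.0154 and 0.196, adjusted p = 0.0331), −0.569 for endothelial (0.0681 and −0.623, adjusted p = 0.000161), −0.453 for Kupffer cell (0.00968 and −0.475, adjusted p = 0.0126) and −0.954 for neutrophil markers (0.65 and −0.362, adjusted p = 0.0331). It was also −1.95 for pancreatic acinar markers (1.32 and −0.337, adjusted p = 0.0129), −0.682 for MHC class II genes (0.0345 and −0.801, adjusted p = 0.0331) and −3.41 for female-biased genes (−0.463 and −3.32, adjusted p = 5.82e-05).

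Single libraries carry many of these differences. Only the female-biased and endothelial lists kept their call without each library in turn. The female-biased median was −0.612 without d63 control replicate 2 and the endothelial −0.856 without d63 early weaned replicate 2. The 3 libraries that lack Y-linked expression lie on the same side of this difference. The female-biased call ended with a Y-linked term (−0.583, camera adjusted p = 0.749) and without these libraries (−0.433, 0.297). In both settings, chosen after seeing the data, the cell cycle, hepatocyte, neutrophil and pancreatic acinar calls ended too. Without d23 control replicate 3, the cell cycle median turned to −0.145, the glucocorticoid median was −0.0373 and the respiratory chain median 0.0823, and all 3 calls ended. The glucocorticoid median was also −0.221, −0.274 and −0.802 without d63 control replicate 1 and early weaned replicates 1 and 3. Without d23 early weaned replicate 3 the cell cycle (1.3) and respiratory chain (0.142) calls ended as well. Without d63 control replicate 1 the MHC class II median turned to 0.0663 and the Kupffer cell median was −0.0373, and the Kupffer cell call also ended without d23 control replicate 3 (−0.304), d23 early weaned replicate 2 (−0.454) or d63 early weaned replicate 1 (−0.325). The unfolded protein response call ended without d23 early weaned replicate 2 (−0.231) or d63 early weaned replicate 1 (−0.261), and the branched-chain call without d23 control replicate 1 (0.249). Of 12 refits, the call ended in 8 for cholesterol synthesis (−0.91 to −0.145), 7 for MHC class II (−1.02 to 0.0663) and hepatocyte markers (0.113 to 0.207), and 6 for neutrophil (−1.65 to −0.413) and pancreatic acinar markers (−7.75 to −0.951). With the Y-linked term the cholesterol median turned to 0.29 and the acinar to 1.86. Without the 3 libraries that lack Y-linked expression they turned to 0.493 and 3.01.

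Chance was not excluded for these differences. Among 100 draws of splits within each age, 19 called as many genes as the real 1 (highest other 4) and 34 as many lists as the real 13 (highest other 22). For every other comparison the 10 splits are too few for a share under 0.05. The number of splits that called as many genes, the real count and the highest other were 2, 2 and 4 at d23, 10, 0 and 2 at d63, 1, 108 and 2 at d211, 1, 54 and 1 for leucine against no leucine, 2, 2 and 4 for leucine against control and 1, 2710 and 1 between ages. For lists they were 8, 9 and 12 at d23, 2, 17 and 18 at d63, 3, 19 and 21 at d211, 1, 16 and 15 for leucine against no leucine, 1, 14 and 13 for leucine against control and 2, 18 and 19 between ages.

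The d63 female-biased genes were weighed against the control library that lacks Y-linked expression. Without that library the median moved from −3.32 to −0.524 (adjusted p = 1.19e-05), so a female animal among the controls is a candidate explanation for most of the size of this difference. The labels do not give sex, and a mislabelled library or a swap is open as well. The remaining −0.524 was not explained.

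At d211 the clock genes were weighed against a difference in the time of day at sampling. Across 19 clock genes the slope on the clock index within groups correlated with the early weaning change at −0.785, but 93% of 2000 random lists treated alike gave a smaller size of correlation, so this stays open. With the clock index as a linear term, the cholesterol synthesis median was 1.4 (camera adjusted p = 1.64e-16) and the beta-oxidation median −0.415 (camera adjusted p = 0.004). The beta-oxidation median with leucine against no leucine fell from 0.203 to 0.0353 and no longer passed. The slope of this term rests on differences within groups. It was carried across a gap between groups, with an index of −4.58 to 2.77 in early weaned and 6.46 to 8.95 in control libraries. The term therefore cannot decide whether clock phase caused these lists. The called genes outside the clock list kept a median share of 0.919 of their change. Of 104 such genes, 49 had the opposite and 55 the same sign as the clock direction (r −0.0149 over the genes outside the list). Yet 1 of 104 stayed past the threshold as the median SE went from 0.216 to 0.411, so phase stays open for single genes too. Feeding before sampling may also set the clock genes; the fatty acid synthesis median was 0.42 in early weaned and 1.04 in leucine livers against controls, and with leucine against no leucine it was 0.288 and not past the threshold (camera adjusted p = 0.053), so feeding and a biological effect of early weaning both stay open.

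Control replicate 3 at d23 had 20 of 25 cell cycle and 21 of 26 PPARα target genes above all of the other 5 d23 libraries. Adult liver RNA in the library would move both directions by 1 share, yet the median share of the way to d63 was 0.0538 over 135 genes high at d63 and 0.977 over 104 genes high at d23, which argues against it. Fasting of this animal would raise the glucocorticoid and PPARα lists together, yet 16 of 19 glucocorticoid targets were below all of the other libraries. That argues against fasting of this animal. It cannot decide on a feeding difference in which the other animals were the fasted ones, because milk fat was not set apart from fasting. Milk feeding, a younger animal and a mislabelled sample were not tested and stay open, and no other biological explanation was tested.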

How the results depend on the processing

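Replicate block, DESeq2, limma, scaling and fits of the compared groups alone were planned, whereas the Y-linked term, leaving out libraries without Y-linked expression, the clock term, counts divided by 4 and leave-one-out for persistence were tests chosen only after the data were seen.

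With 3 libraries per group, most gene counts moved with the tool or with a single library; the cause was not tested for these counts unless named. The directions of the d211 lists were steadier: beta-oxidation, PPARα targets and cholesterol synthesis kept their direction under every setting tried, and their camera calls in all 6 refits without a library. Depth limits genes near the floor of 12 count units, and its effect on the lists was not tested. Every alternative fixed beforehand was run.

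With an estimated correlation in camera, 0 lists were called at d23, d63, d211, for leucine against no leucine, for leucine against control, for the interaction and between ages. Fry called 1, 0, 4, 3, 0 and 0 lists for these contrasts before age. Neither moves a median, so the lists no longer called keep −0.399 (PPARα) and 0.573 (cholesterol) at d23, −0.684 (PPARα) at d63, −0.396 (beta-oxidation), −0.479 (PPARα) and 1.27 (cholesterol) at d211, and 0.203 (beta-oxidation) and −0.57 (cholesterol) with leucine.

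With a fold minimum of 2, 1683 genes were called between ages. Without a count filter, 5 genes were called at d23, 113 with leucine against no leucine and 5 against control. DESeq2 called 116 at d23, 89 at d63, 45 in the interaction and 4133 between ages. At d211 it called 1123, with leucine 781 and with leucine against control 201. On simulated data it called more unchanged genes than edgeR and also recovered more of the changed ones. Counts divided by 4 gave 188 at d211 and 154 with leucine. Fits of the compared groups alone, which have fewer samples, gave 1 at d23, 2 at d63, 281 between ages, 31 at d211, 32 with leucine and 4 against control.

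With limma on log2(FPKM + 1), 6 genes were called at d23, 2 in the interaction, 328 at d211 and 136 with leucine, and the correlation between d63 and d211 changes was −0.188. With a pseudocount of 0.1 these were 4 at d23, 2 at d63, 221 at d211, 8 lists in the interaction and −0.188. Without a filter they were 12 at d23, 1 at d63, 3 in the interaction, 6 at d211, 15 with leucine, 4 against control and −0.171, and the beta-oxidation median with leucine was 0.0513. On TPM they were 9 at d23, 2 in the interaction, 615 at d211, 173 with leucine and −0.178, and that median was 0.0208. With median-of-ratios size factors they were 5 at d23, 2 in the interaction, 97 with leucine, 5 against control and −0.199. The median of all genes moved by −0.122 on FPKM and −0.153 on TPM in the interaction.

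The replicate numbers showed no clear pairing of the samples: correlations between same-number samples passed 0.1 in 1 of 6 Wistar pairs and 1 of 9 Sprague Dawley pairs. The highest Wistar value was 0.127 for same-number and 0.0903 for other pairs. For Sprague Dawley pairs these were 0.122 and 0.127. With 3 samples per group, this cannot exclude pairing by replicate number. With the number as a block, 1 gene was called at d23, 1 at d63, 0 in the interaction (edgeR, 614 at an unadjusted p under 0.05; DESeq2 without a block called 45), 360 between ages, 49 at d211 and 5 with leucine against control.

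With a term for Y-linked expression, 0 genes were called at d23 by edgeR (717 at an unadjusted p under 0.05; DESeq2 without the term called 116), 1 at d63 and 1559 between ages. The cholesterol median was 0.056 at d23 and 0.283 at d63, and reversed to 0.29 in the interaction, and the correlation between d23 and d63 changes reversed to −0.102. Without the 3 libraries that lack Y-linked expression, 1 gene was called at d23, 1 at d63, 2 in the interaction and 623 between ages, 6 lists were called in the interaction, and the cholesterol median reversed to −0.235 at d23 and 0.493 in the interaction. The cause was not tested.

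With the clock index as a term, 1 gene was called at d211, 0 with leucine by edgeR (959 at an unadjusted p under 0.05; DESeq2 without the term called 781) and 4 against control. With leucine 10 lists were called, the beta-oxidation median was 0.0353, the circadian 0.393 and the xenobiotic 0.197, all no longer past the threshold, and the correlation between early weaning and leucine changes was −0.851. At d211 the calls of the fatty acid (0.471) and xenobiotic lists (−0.343) ended. So did those of the glycolysis (−0.354), ATF4 (−0.426), male-biased (−0.438), heat shock (−0.117), respiratory chain (−0.12) and ribosomal protein lists (−0.0777). The median SE of called genes rose with this term.

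Leaving out each library in turn, which assumes that the remaining samples vary like the other groups, gave these ranges. At d23, 1 to 6 genes and 2 to 12 lists were called, with medians of −0.61 to 0.165 for beta-oxidation, −0.649 to 0.124 for PPARα targets, 0.16 to 0.854 for cholesterol synthesis and −0.0183 to 0.613 for glucocorticoid targets. At d63, 0 to 3 genes were called, with −0.163 to 0.0248 for beta-oxidation, −0.498 to 0.371 for cholesterol synthesis, 0.175 to 1.05 for male-biased genes, −1.26 to 0.0197 for MHC class II and −1.81 to 0.418 for erythroid markers. In the interaction, 0 to 4 genes and 6 to 16 lists were called, with −1.02 to 0.0663 for MHC class II. Between ages, 646 to 6001 genes were called. At d211, 2 to 534 genes were called. With leucine against no leucine, 1 to 539 genes were called, with 0.0768 to 0.307 for beta-oxidation and −0.353 to −0.125 for PPARα targets. With leucine against control, 2 to 6 genes were called, with 0.0131 to 0.691 for Kupffer cell markers. The correlation between d23 and d63 changes ran from −0.00844 to 0.093.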

Other observations

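The tests by list were planned, whereas the values per library for Spsb2, Asb15, Clock, Dbp, Arntl and the d23 control libraries were chosen only after they were seen.

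Against controls, early weaned livers with leucine at d211 had all 12 heat shock genes lower (median −0.628, camera adjusted p = 5.48e-09; adjusted p = 0.207 with an estimated correlation), and 5 fell when adjusted over the list alone, with a median of −0.397 without control replicate 3. ATF4 target genes of the amino acid response were lower in 18 of 21 cases (median −0.678, camera adjusted p = 7.74e-07; adjusted p = 0.207 with an estimated correlation), with a median of −0.392 without control replicate 2. Urea cycle genes were higher (median 0.415, camera adjusted p = 3.28e-05; adjusted p = 0.478 with an estimated correlation), and so were all 5 skeletal muscle markers (median 2.03, camera adjusted p = 0.0385; adjusted p = 0.49 with an estimated correlation). The muscle call ended without leucine replicate 2 (median 1.54) or 3 (1.9), and the median was 3.9, 3.2 and 3.72 without control replicates 1 and 3 and leucine replicate 1. Without leucine, ATF4 targets were lower than in controls (median −0.545, camera adjusted p = 0.0183; adjusted p = 0.361 with an estimated correlation), as were genes of glycolysis and gluconeogenesis (median −0.275, camera adjusted p = 0.00646; adjusted p = 0.232 with an estimated correlation). The ATF4 call ended without control replicate 2 (median −0.291) or early weaned replicate 2 (−0.428), and the glycolysis call without control replicate 1 (−0.276). Heat shock genes were lower without leucine too, in 10 of 12 cases (median −0.229, camera adjusted p = 0.00142; adjusted p = 0.292 with an estimated correlation), with −0.364, −0.146 and −0.347 without control replicates 1 and 3 and early weaned replicate 1. Of the sex-biased lists, both were lower without leucine than in controls. Male-biased genes were lower in 8 of 9 cases (median −0.482, camera adjusted p = 0.00646; adjusted p = 0.231 with an estimated correlation), with −0.818 and −0.182 without early weaned replicates 2 and 3. Female-biased genes were lower in 8 of 9 cases (median −2.2, and −1.43 with genes at 0 set to their bound; camera adjusted p = 2.49e-05; adjusted p = 0.231 with an estimated correlation), with a median of −1.18 without control replicate 2, and Cyp2c12 had 1.75 (adjusted p = 0.0724). Only 1 gene was set to its bound, and how far the female-biased median rests on other genes near the floor was not tested.

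At d63, immune genes were lower in early weaned livers, with 9 of 9 MHC class II genes (median −0.801, camera adjusted p = 0.00422; adjusted p = 0.454 with an estimated correlation), 11 of 12 T and NK cell markers (median −0.904 with genes at 0 set to their bound, camera adjusted p = 0.00244; adjusted p = 0.311 with an estimated correlation) and 20 of 23 interferon-response genes (median −0.28, camera adjusted p = 0.00751; adjusted p = 0.524 with an estimated correlation). Without control replicate 1 the MHC class II median was 0.0197, the call of the T and NK cell markers ended (−0.66) and so did that of the interferon genes (−0.204). The interferon call also ended without control replicate 2 (−0.195) or early weaned replicate 1 (−0.171), with −0.493 without early weaned replicate 2. The MHC class II call also ended without early weaned replicate 1 (−0.781), and its median was −1.26 without control replicate 2. At d23, glucocorticoid targets were higher (median 0.366, camera adjusted p = 0.00832; adjusted p = 0.696 with an estimated correlation), and their median was −0.0183 without control replicate 3, 0.279 and no longer past the threshold without early weaned replicate 2, and 0.613 without control replicate 2. Between d23 and d63, 22 of 33 respiratory chain genes fell (median −0.632, camera adjusted p = 1.18e-08; adjusted p = 0.479 with an estimated correlation), as did 11 of 20 matrix genes (median −0.976, camera adjusted p = 2.42e-08; adjusted p = 0.254 with an estimated correlation), while 7 of 9 male-biased genes (median 9.68, camera adjusted p = 0.000346; adjusted p = 0.469 with an estimated correlation) and 6 of 9 MHC class II genes rose (median 2.97, camera adjusted p = 0.000917; adjusted p = 0.471 with an estimated correlation; 1.82 without d63 control replicate 1).

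Other lists were called and are given by direction alone. At d23 these were urea cycle genes, higher, a call that ended without control replicate 3 (median 0.0467) and with the Y-linked term (0.0601). At d63 they were tricarboxylic acid cycle and mitochondrially encoded genes, higher, and matrix, unfolded protein response and erythroid genes, lower. The unfolded protein response call ended in 3 of 6 refits without a library and the mitochondrially encoded call in 2. The erythroid median turned to 0.418 without control replicate 3. At d211 they were respiratory chain and ribosomal protein genes, lower in early weaned livers than in controls by the main test. The respiratory chain call ended with limma on FPKM (median 0.0449) and on TPM (0.126), where the median turned positive. The ribosomal protein call ended with limma on TPM (0.0658) and without a filter (−0.0152). With leucine against no leucine they were glycolysis, tricarboxylic acid cycle, mitochondrially encoded, matrix and female-biased genes, all higher. The matrix call ended in 4 of 6 refits without a library, the tricarboxylic acid cycle call in 2 and the mitochondrially encoded and female-biased calls in 1 each. The tricarboxylic acid cycle median was −0.0375 with limma on TPM and −0.00721 with limma without a filter. With leucine against control they were glucocorticoid, growth hormone, mitochondrially encoded and ribosomal protein genes, all lower. Without a library in turn, the glucocorticoid and mitochondrially encoded calls each ended in 3 of 6 refits and the growth hormone call in 2. The glucocorticoid median was 0.0489 without control replicate 2. Between ages they were bile acid, sterol efflux, antioxidant and unfolded protein response genes, higher, and glucocorticoid, fetal, tricarboxylic acid cycle, mitochondrially encoded, ribosomal protein and endothelial genes, lower. The bile acid call between ages ended in 3 of 6 refits without a library and in 12 of 20 alternatives in all. The endothelial call ended in 2 of 6 and 8 of 20, and the fetal call in 1 of 6 and 6 of 20. None of the lists given by direction alone was called with an estimated correlation.

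Spsb2 was near all-or-none across the Wistar libraries too, at 1.46 FPKM in d23 early weaned replicate 3, 3.27 and 3.81 in d63 control replicates 1 and 3, 3.14 in d63 early weaned replicate 1 and a count of 0 in the other 8. Asb15 was at 1.73, 2.03 and 2.15 FPKM in the d23 early weaned libraries, a count of 0 in the d23 controls (at least 42.2-fold, adjusted p = 0.0602, not past the threshold) and 1.83 in leucine replicate 3 at d211. Clock was at 2.56, 2.55 and 2.22 FPKM in d211 controls, 0.506, 0.673 and 0.282 in early weaned livers and 0.459, 0.469 and 0.265 with leucine, and ran from 0.31 to 3.0 in the Wistar libraries. Dbp, a clock output gene, was at 72.6, 68.6 and 139 FPKM in d211 controls, 0.871, 0.993 and 14.6 in early weaned livers and 81.5, 67.8 and 175 with leucine, and Arntl at 3.23, 1.89 and 1.11, 10.6, 10.3 and 7.21, and 2.78, 3.45 and 0.545.

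In d23 control replicate 3, Igfbp1 was at 473 FPKM, where the other d23 libraries had 5750 to 8430, and albumin took 18.1% of counts, where they had 7.16% to 11.2%. Contrasts that share the d211 controls correlated at 0.491 across genes. Simulated sets without group effects, with each gene drawn independently, gave 0.499 (0.453 to 0.542).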
